A study of Mus musculus with 6 samples.

How the data were processed

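Gene expression was measured by RNA sequencing of total RNA from snap frozen liver of C57BL/6 mice, with libraries made with a TruSeq RNA kit, per the labels' protocols. The labels give 2 groups. Mice of the diet group received a high fat (Western) diet for 3 months, and mice of the dabigatran group received the same diet with 10 mg of dabigatran etexilate per gram. Replicates carry the numbers 0, 1 and 2 in the labels of each group, and only the word mice in the design text, which gives 3 per group, says that replicates are separate animals.

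Each deposited file lists 23291 gene symbols with 1 FPKM value each (fragments per kilobase of gene, scaled to the mapped fragments of the library), the unit given per the file headers. CASAVA, TopHat2 2.0.4, TopHat, Cuffdiff and R 2.15.1 are named in the submitters' processing notes with no role or order, together with the builds mm10 and GRCm38. The gene annotation, the handling of reads that match several genes, the use of strand and the scaling between libraries are not given in the sources used here. FPKM divides by a gene's length and by the total of a library. A few very abundant genes can therefore lower the values of the others, and the 10 most abundant genes held 20.7% to 24.5% of the summed FPKM of a library.

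The files of dabigatran replicates 0 and 1 held identical values for all 23291 genes, and the replicate number inside both files was 1. They were counted as 1 library, called dabigatran replicate 1, so the comparison rests on 3 diet libraries and 2 dabigatran libraries. The test had been planned for 3 libraries per group and a filter over 6 libraries. Dabigatran replicate 0 was not analysed here.

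The planned count tests were not run, because the deposited unit is FPKM. Depth was read from the steps of the low values: among genes under 0.3 FPKM, the most common ratio between libraries gives the relative value of 1 fragment. The resulting depth relative to diet replicate 0 was 0.761 for diet replicate 1, 0.967 for diet replicate 2, 0.857 for dabigatran replicate 1 and 0.772 for dabigatran replicate 2. With these ratios, 8295 of the 10247 tested genes (81.0%) had values that were whole multiples of a common step within a relative tolerance of 2e-05, against 1.1% of 1000 genes whose values were randomly shifted. Fragments given for a gene are the smallest whole numbers in the observed ratio, and the true numbers can be a multiple of them. They cover counting error only. On this scale a library held 928283 to 1207773 fragments in these genes, and the median gene had 33 to 43.

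An exact 0 in these files can be a failed estimate. The genes Rpl30, Ndufs5 and Ass1, which encode a ribosomal protein, a subunit of respiratory complex I and a urea cycle enzyme, were each listed at 0 in some library and above 10 FPKM in another. In all, 24 genes were listed at 0 in a library and above 20 FPKM in another, of which 10 were microRNA or small nucleolar RNA genes. Genes with such values are described as listed at 0, with each library's value.

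Genes with at least 1 FPKM in at least 3 of the 5 distinct libraries were tested, 10247 in all. Values were log2(FPKM + 0.5), and limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) tested the dabigatran group against the diet group, with group as the sole term. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes and log2 differences are on the log2(FPKM + 0.5) scale, which understates the change of low genes. SD is given on the FPKM scale and SE on the log2 scale. The same steps were tested on simulated data for 3 against 2 libraries of 10247 genes, with 200 genes changed. They recovered 17.2% of 2-fold, 82.6% of 4-fold and 99.1% of 16-fold changes, and 4.8% of calls were false. The simulated genes varied independently with normal errors, as the fit assumes. These rates therefore do not cover correlated genes, values listed at 0 or an outlying library.

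A total of 32 gene lists was written before the data were examined, and 25 of them had at least 5 tested members. Shifts of these lists were tested with limma's camera (preset inter-gene correlation of 0.01), adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. The estimated version uses the 3 residual degrees of freedom of the fit and so has little power here. Fry's directional p is given unless said otherwise. Members count as risen or fallen by the adjusted p over all tested genes, and the count adjusted over the list alone stands beside it. Genes are named by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called genes whose libraries did not overlap between the groups and whose mean was at least 1 FPKM in the higher group. To these come up to 4 members of each list in order of unadjusted p, and F2, F2r, Fga, Fgb, Fgg, Cd36, Pparg, Cidea, Cidec, Cyp7a1, Ccl2 and Col1a1 whatever their p. Other genes named were chosen after their values were seen.

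Coordinates are those of RefSeq on GRCm38.p6, with 20775 of the 23291 symbols matched directly and 2264 through a synonym of 1 gene. Exon overlaps and the share of 50-base windows that also occur in transcripts of other genes were taken from GENCODE vM21 on GRCm38 for the genes named by the rule. Besides those given in the text, exons overlap a gene on the opposite strand for Abcg5, Arntl, Ccnd1, Cdkn1a, Clec4g, Dbp, Fgg, Fn1, Gbp2, Hmgcs1, Idi1, Me1, Ndufa2, Nr1d1, Plin4 and Psmb8, and a gene on the same strand for Col3a1, Ndufb8 and Serpina3m, so reads of these pairs may not be separable. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Alternatives tried were a block on the replicate number, each library left out in turn, other pseudocounts, filters and scalings, no variance trend, a robust prior and an estimated correlation. Only the diet group has a distinct replicate 0. The block therefore takes diet replicate 0 out of the comparison and is not independent of leaving that library out. Added after the data were seen were the filter with 2 libraries, the identical files counted as 2 libraries, a threshold of 0.10, genes listed at 0 left out, limma's voom on the whole fragments, and the same limma fit on the genes with whole fragments only.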

Results

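RNA sequencing of mouse liver addressed which hepatic genes differ when a thrombin inhibitor is added to a high fat diet. Dabigatran etexilate is an oral prodrug that carboxylesterases cleave to dabigatran, a direct inhibitor of thrombin. The diet group had 3 libraries (replicates 0, 1 and 2). The dabigatran group had 3 deposited tables, of which those of replicates 0 and 1 were identical for all 23291 genes and were counted as 1 library, which leaves n = 2. Between 10006 and 10399 genes reached 1 FPKM in a library. Depth, relative to diet replicate 0, ranged from 0.761 in diet replicate 1 to 0.967 in diet replicate 2, with 0.857 and 0.772 in dabigatran replicates 1 and 2.

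Neither the diet nor the dabigatran libraries formed a tight group. Across genes, log2 values of the 2 dabigatran libraries had a correlation of 0.976. Diet replicate 1 had 0.9776 with dabigatran replicate 1, beside 0.9789 and 0.9764 with diet replicates 0 and 2. On the first principal component of the 10247 tested genes, which held 49.2% of the variance, diet replicates 0 and 2 lay at -29.5 and -28.8, diet replicate 1 at -6.16, and dabigatran replicates 1 and 2 at 15.8 and 48.7. The lipid droplet gene Cidea had 95.04 and 98.7 FPKM in diet replicates 0 and 2 but 2.17 in diet replicate 1, and the desaturase gene Scd1 had 5185 and 3633 FPKM against 1432.

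**Figure D1:**
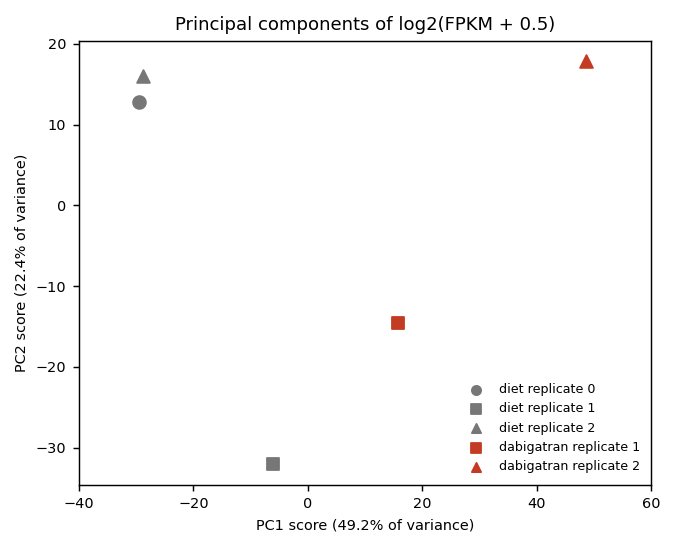
Scores of the 5 distinct libraries on the first and second principal components of log2(FPKM + 0.5), with the share of variance on each axis; grey points are diet libraries and red points dabigatran libraries. Diet replicate 1, at -6.16 on the horizontal axis, sits between diet replicates 0 and 2 (-29.5 and -28.8) and dabigatran replicate 1 (15.8).

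Among the gene lists lower in the dabigatran group by camera with its preset correlation were fatty acid oxidation genes and PPAR alpha targets, carboxylesterases and interferon-stimulated genes. With an estimated correlation 0 lists passed (adjusted p = 0.485, 0.679 and 0.679 for these lists). Of their members, 4 of 33, 1 of 12 and 0 of 23 passed over all genes. The estimated correlations were -0.007, 0.281 and 0.322. The first lies below the preset 0.01, so a higher correlation did not end the call of that list. With an estimate, camera also uses the 3 residual degrees of freedom of the fit, which leaves it little power. Of the 10247 tested genes, 31 fell and 13 rose with dabigatran (limma, adjusted p under 0.05), against 16 and 11 after quantile normalization and 10 and 10 with voom on the 8295 genes with whole fragments, where the same limma fit gave 30 and 14. Among the falls were Cfd, Car3, Pparg, Fabp1 and Vnn1, and among the rises Cyp17a1, Mt1, Sds, Sdsl and Acacb. The groups did not overlap in any of the 44 called genes, nor in 34.4% of all tested genes, against 20% by chance with 3 and 2 libraries. At an unadjusted p under 0.05, 704 genes were higher and 936 lower, where chance gives 512.4 in all. The gene calls depended on single libraries: without diet replicate 0, diet replicate 2 or dabigatran replicate 2, limma called 0 genes, with 440, 485 and 324 higher and 586, 576 and 672 lower at an unadjusted p under 0.05. Without diet replicate 1, 88 rose and 178 fell, and without dabigatran replicate 1, 101 rose and 229 fell.

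The largest fitted fall was that of Cfd (chromosome 10, 79890853 to 79892655), which encodes complement factor D, also called adipsin. Its values were 150.4, 28.3 and 47.5 FPKM in diet replicates 0, 1 and 2, and it was listed at 0 in both dabigatran libraries (adjusted p = 0.0110). Car3 (chromosome 3, 14863538 to 14872381), a carbonic anhydrase abundant in liver and fat, fell from 1303 ± 673 FPKM (SD, n = 3) to 111 ± 26.3 (SD, n = 2), a log2 difference of -3.38 ± 0.48 (SE, adjusted p = 0.0404). Diet replicate 1 had the lowest diet value of both genes, with 526 FPKM for Car3.

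Hsd17b6 and Serpina6 were among the other large falls. Hsd17b6 (chromosome 10, 127990931 to 128007648), a hydroxysteroid dehydrogenase gene, fell from 48.2 ± 13.6 FPKM (SD, n = 3) to 5.42 ± 0.148 (SD, n = 2), with a log2 difference of -3.00 ± 0.26 (SE, adjusted p = 0.0110). Serpina6 (chromosome 12, 103646630 to 103657218), which encodes corticosteroid-binding globulin, fell by 2.32 on the log2 scale. The long noncoding RNA gene 1500017E21Rik (now Hectd2os, chromosome 19, 36619418 to 36689479) fell by 3.36, but its exons overlap Hectd2 on the opposite strand, so reads of the pair may not be separable without strand. The same limit holds for the called genes Sds, Acaa1b, Ctgf and Nrbp2, whose exons overlap Gm15690 and Plbd2, Dlec1, Gm15270 and Gm48952 on the opposite strand. The zinc finger gene Gm13152 (now Zfp982), the protease inhibitor gene Serpinb1a and the water channel gene Aqp4 fell by 2.21, 2.38 and 2.19 on the log2 scale. Gm4013, Lst1 and Ly6c1 were listed at 0 in both dabigatran libraries. In diet replicates 0, 1 and 2 they had 7.66, 7.54 and 1.98 FPKM (Gm4013), 5.74, 7.54 and 1.98 (Lst1), and 1.91, 3.25 and 2.55 (Ly6c1). Gm4013 and Lst1 rest on 4, 3 and 1 and on 3, 3 and 1 fragments, and 32.8% of the 50-base windows of Ly6c1 also occur in other genes, mostly Ly6c2.

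The largest fitted rise was that of E030018B13Rik (chromosome 7, 63916857 to 63920539). It was listed at 0 in diet replicate 0, with 2.57 and 0.507 FPKM in diet replicates 1 and 2, and had 38.8 and 68.5 FPKM in the dabigatran libraries (adjusted p = 0.0404). Eif4ebp3 (chromosome 18, 36664060 to 36666324), a repressor of cap-dependent translation, rose from 17.0 ± 4.94 FPKM (SD, n = 3) to 163 and 738 in dabigatran replicates 1 and 2, a log2 difference of 4.35 ± 0.55 (SE, adjusted p = 0.0404). Of its windows, 65.5% are shared with an annotated transcript that joins it to its neighbour, so its value is uncertain. Cyp17a1 (chromosome 19, 46667165 to 46673000), a steroid hydroxylase gene, rose 9.28-fold, from 3.42 ± 1.58 FPKM (SD, n = 3) to 35.9 ± 16.9 (SD, n = 2). The oxysterol hydroxylase gene Cyp39a1 rose 5.08-fold and the metallothionein gene Mt1 4.65-fold, the latter from 128 ± 18.0 to 637 ± 339 FPKM (SD, n = 3 and n = 2). St3gal5, which encodes the enzyme that makes the ganglioside GM3 from lactosylceramide, rose 4.30-fold, and Nrbp2 3.28-fold. The uncharacterised gene 1810010H24Rik rose by 2.44 on the log2 scale on 1 or 2 fragments per diet library and 10 and 11 in the dabigatran libraries.

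**Figure D2:**
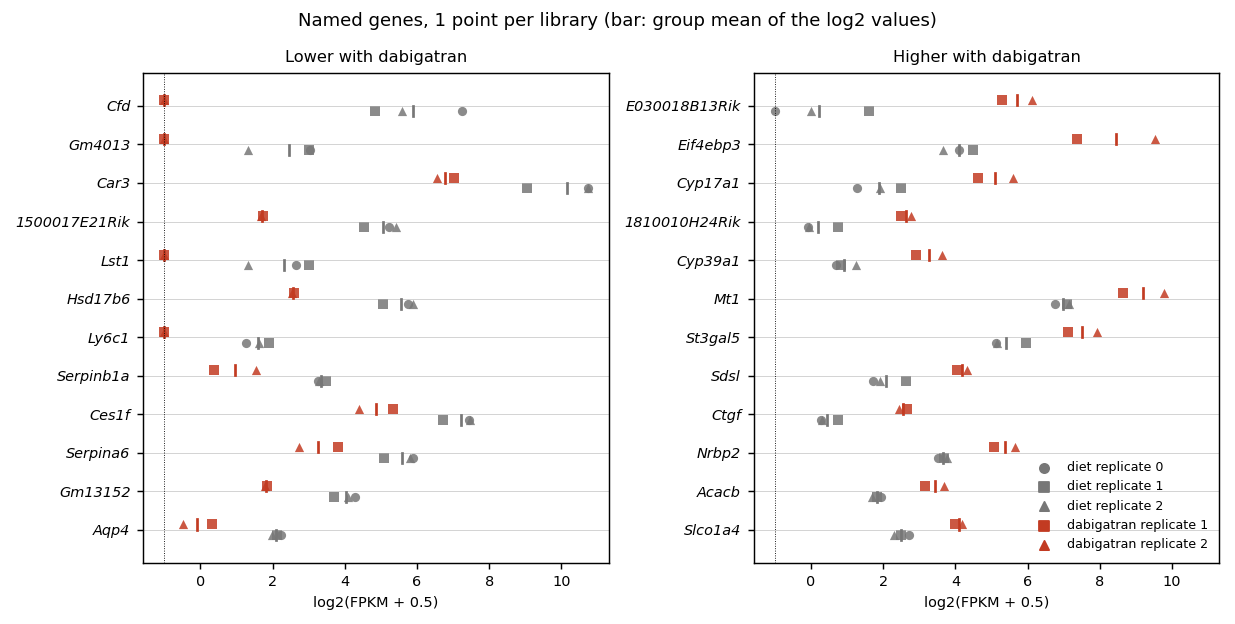
Expression of the 12 largest falls and 12 largest rises, as log2(FPKM + 0.5) on the horizontal axis, with 1 point per library (grey, diet; red, dabigatran) and a bar at each group's mean of the log2 values; the dotted line marks an FPKM of 0. By the rule that chose these genes, no dabigatran point overlaps the diet points of its gene. Cfd, Gm4013, Lst1 and Ly6c1 lie at 0 in both dabigatran libraries.

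Genes of lipid droplets and fat uptake were lower as a list. Of 21 measured members, 1 fell and none rose, against 7 lower and 2 higher when adjusted over the list alone. The median log2 difference was -0.35 (camera adjusted p = 0.0316, and adjusted p = 0.679 with an estimated correlation). The member that fell was Pparg, the nuclear receptor that drives fat storage, from 7.21 ± 1.66 FPKM (SD, n = 3) to 1.33 ± 0.306 (SD, n = 2; adjusted p = 0.0404). The fatty acid transporter gene Cd36 had 95.2 ± 42.4 FPKM in the diet group and 24.0 ± 8.81 with dabigatran (adjusted p = 0.0942), and Plin4 had 13.7 ± 5.82 and 3.53 ± 1.12 (adjusted p = 0.101). Cidea was listed at 0 in dabigatran replicate 1 and had 0.438 FPKM in replicate 2, below all diet values (adjusted p = 0.127), and Cidec had 35.9 ± 13.5 and 23.2 ± 0.104 FPKM (adjusted p = 0.459). In diet replicate 1 the list's median lay 0.22 below the diet mean on the log2 scale, at -0.22, beside -0.40 and -0.30 in the dabigatran libraries. The call was lost without diet replicate 0 (median -0.29, adjusted p = 0.119), diet replicate 2 (-0.21, 0.212) or dabigatran replicate 1 (-0.30, 0.0826), and with an FPKM of at least 5 (median -0.45), while the median was -0.54 without a filter on low values.

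Fatty acid synthesis genes were lower as a list, while 1 of the 24 members rose and none fell. Adjusted over the list alone, 3 were lower and 1 higher. Acacb, the mitochondrial acetyl-CoA carboxylase whose product restrains fatty acid import into mitochondria, rose from 3.04 ± 0.313 FPKM (SD, n = 3) to 10.4 ± 2.67 (SD, n = 2; adjusted p = 0.0464). Scd1 had 3416 ± 1886 FPKM in the diet group and 370.0 ± 327 with dabigatran (adjusted p = 0.0751), the malic enzyme gene Me1 (22.9% of windows shared, mostly with Gm7049) had 45.3 ± 14.7 and 14.6 ± 4.76, and the elongase gene Elovl6 10.1 ± 0.418 and 5.08 ± 0.639. The list's median was -0.39 (camera adjusted p = 0.0316, and adjusted p = 0.679 with an estimated correlation), and diet replicate 1, at -0.35, lay at the level of the dabigatran libraries (-0.22 and -0.34). Leaving out any library other than diet replicate 1 ended the call, with adjusted p of 0.142, 0.137, 0.0826 and 0.120 without diet replicates 0 and 2 and dabigatran replicates 1 and 2, and medians of -0.23, -0.24, -0.34 and -0.22. The fit without a variance trend (median -0.39) ended it too. So did a block on the replicate number (-0.23), which sets diet replicate 0 aside much as leaving it out does.

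Fatty acid oxidation genes and PPAR alpha targets were lower as a list. Of 33 measured members, 4 fell and none rose, against 9 lower and 4 higher when adjusted over the list alone, with a median log2 difference of -0.25 (camera adjusted p = 8.00e-04, and adjusted p = 0.485 with an estimated correlation). Fabp1, the liver fatty acid binding protein, fell from 10527 ± 194 FPKM (SD, n = 3) to 2544 ± 1114 (SD, n = 2; adjusted p = 0.0404). Vnn1, a pantetheinase, fell from 81.8 ± 7.35 to 24.8 ± 2.98 FPKM (adjusted p = 0.0279) and Aldh3a2, a fatty aldehyde dehydrogenase, from 323 ± 52.4 to 94.9 ± 15.4 (adjusted p = 0.0404). The peroxisomal thiolase gene Acaa1b fell from 857 ± 163 to 267 ± 32.6 FPKM, with 30.5% of its windows shared, mostly with Acaa1a. The omega-hydroxylase genes Cyp4a10, Cyp4a14 and Cyp4a31, classic PPAR alpha targets, had log2 differences of 1.00, 1.71 and 1.69, opposite to the list, and passed when adjusted over the list alone but not over all genes. The 3 diet libraries lay close together for this list (-0.03, -0.01 and 0.01), below which were dabigatran replicates 1 and 2 (-0.35 and -0.19).

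Among 12 carboxylesterases, enzymes of the family that activates the prodrug, 1 fell and none rose, with 4 lower when adjusted over the list alone. Ces1f fell from 151 ± 40.3 FPKM (SD, n = 3) to 30.3 ± 13.6 (SD, n = 2; adjusted p = 0.0404), while Ces1e had 54.6 ± 19.2 and 18.4 ± 0.479, and Ces2e 86.3 ± 32.0 and 30.7 ± 2.48. The median was -0.99 (camera adjusted p = 9.21e-04, and adjusted p = 0.679 with an estimated correlation), and -0.63 without a filter on low values. The AhR and NRF2 target genes had a median of -0.45 over 18 members (camera adjusted p = 0.00536, and adjusted p = 0.679 with an estimated correlation). None of them passed over all genes and 5 were lower when adjusted over the list alone, among them Gclc, for glutathione synthesis (90.8 ± 21.9 and 26.9 ± 16.3 FPKM), and Osgin1 (56.5 ± 11.9 and 20.1 ± 4.96). The median of the AhR and NRF2 targets was -0.23 without dabigatran replicate 2 and -0.25 without a filter on low values. The groups overlapped for this list: diet replicates 0, 1 and 2 lay at 0.03, -0.28 and 0.16, and dabigatran replicates 1 and 2 at -0.23 and -0.61. The CAR and PXR target genes had a median of -0.65 over 18 members, with none passing over all genes and 6 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.0348, and adjusted p = 0.679 with an estimated correlation). Cyp3a11 had 1062 ± 537 and 240.5 ± 166 FPKM and Aldh1a1 791 ± 289 and 296 ± 77.2, whereas Por, the electron donor of the cytochromes P450, had 72.4 ± 2.22 and 219 ± 105. The CAR and PXR call was lost without diet replicate 0 (median -0.40, adjusted p = 0.119), diet replicate 2 (-0.38, 0.137) or dabigatran replicate 1 (-0.67, 0.324), and its median was -0.42 without dabigatran replicate 2. The call also ended with an FPKM of at least 5 (median -0.43), without a variance trend (-0.65) and after quantile normalization (-0.62), while among genes with whole fragments only the median was -1.09.

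Bile acid genes had differences in both directions and were not called as a list (21 measured, median -0.04, mean 0.07, camera adjusted p = 0.861 in the downward direction). Slco1a4, a transporter for bile acids and organic anions, rose from 5.22 ± 0.856 FPKM (SD, n = 3) to 16.6 ± 1.70 (SD, n = 2; adjusted p = 0.0404). Adjusted over the list alone, 6 members were higher and 5 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 15.6 ± 7.30 FPKM in the diet group and 35.2 and 267 in dabigatran replicates 1 and 2 (adjusted p = 0.149). The export genes Abcg5 (59.0 ± 1.08 and 26.4 ± 6.72) and Abcc3 (56.0 ± 20.6 and 16.0 ± 1.11) and the uptake gene Slco1b2 (461 ± 39.4 and 276 ± 7.52) were lower in each dabigatran library than in any diet library, without passing over all genes. Cholesterol synthesis genes had a median of 0.12 over 21 members, none of which passed by either adjustment (camera adjusted p = 0.278). Idi1 had 5.04 ± 0.371 and 12.5 ± 6.72 FPKM and Hmgcs1 26.9 ± 7.26 and 12.4 ± 5.54.

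Interferon-stimulated genes had the lowest p of the 25 lists with camera's preset correlation, but not with the estimated correlation or with fry. The median log2 difference over 23 measured members was -0.88 (camera adjusted p = 4.21e-08, and adjusted p = 0.679 with an estimated correlation), and 22 of the 23 members had lower values with dabigatran. None passed over all genes, and 11 were lower when adjusted over the list alone. The guanylate binding protein genes Gbp2 (5.33 ± 1.51 and 1.06 ± 0.531 FPKM) and Gbp3 (5.83 ± 1.93 and 1.57 ± 0.729), the tetherin gene Bst2 (133 ± 23.2 and 74.6 ± 6.81) and the immunoproteasome gene Psmb8 (17.0 ± 1.08 and 5.32 ± 4.67) had the lowest p. Against the diet mean, the list lay at -0.48 in dabigatran replicate 1 and -1.04 in replicate 2, and at 0.33, -0.12 and -0.02 in the diet libraries. Without dabigatran replicate 2 the median was -0.48. Cytokine and chemokine genes had a median of -0.20 over 14 members (camera adjusted p = 0.390). None passed over all genes and 1, the chemokine gene Cxcl9 (9.97 ± 5.14 and 1.37 ± 0.736 FPKM), was lower when adjusted over the list alone. Cxcl10 was listed at 0 in dabigatran replicate 2, with 2.07 FPKM in replicate 1 and 6.64, 1.16 and 7.33 in the diet libraries. Ccl2, not tested because of its low values, had 1.32, 0.869 and 5.47 FPKM in the diet libraries and was listed at 0 in both dabigatran libraries.

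Markers of macrophages and Kupffer cells were lower as a list, with a median of -0.32 over 26 members (camera adjusted p = 0.0279, and adjusted p = 0.679 with an estimated correlation). No marker passed over all genes, and 6 were lower and 2 higher when adjusted over the list alone. The antigen presentation genes H2-Aa (59.6 ± 16.3 and 19.2 ± 5.35 FPKM), H2-Ab1 (26.8 ± 6.42 and 10.1 ± 0.397) and H2-Eb1 (28.8 ± 10.7 and 9.19 ± 2.61) had low values, and the scavenger receptor gene Cd163 high ones (4.34 ± 1.54 and 12.6 ± 0.876). Dabigatran replicate 2 set this shift: the list lay at -0.64 there and at 0.03 in replicate 1. The median was 0.03 without dabigatran replicate 2 (adjusted p = 0.913), and without diet replicate 2 the call was also lost (-0.13, 0.146). Without dabigatran replicate 1 the median was -0.64, and the call ended with the identical files counted as 2 libraries (-0.15).

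Acute phase genes had a median of 0.24 over 23 members (camera adjusted p = 0.0892), with none passing over all genes and 3 higher when adjusted over the list alone. The list passed when genes listed at 0 were left out (median 0.27) and with the identical files counted as 2 libraries (0.40). The higher members were Itih3 (209 ± 50.3 and 531 ± 43.0 FPKM), Serpina3m (113 ± 31.1 and 292 ± 92.1) and Serpina3n (199 ± 73.6 and 481 ± 60.3). This list depended on single libraries: it lay at 0.68 in dabigatran replicate 1 and -0.14 in replicate 2. It passed without diet replicate 1 (0.55, adjusted p = 0.00509) and without dabigatran replicate 2 (0.68, adjusted p = 3.91e-06).

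Genes of glucose metabolism and insulin signalling were higher as a list, with 1 of 23 members risen, none fallen and 3 higher when adjusted over the list alone (median 0.28, camera adjusted p = 0.0312, and adjusted p = 0.679 with an estimated correlation). Sds, serine dehydratase, which feeds serine into gluconeogenesis, rose from 62.7 ± 4.06 FPKM (SD, n = 3) to 152 ± 6.21 (SD, n = 2; adjusted p = 0.0404). Its neighbour and relative Sdsl rose 4.29-fold. The tyrosine aminotransferase gene Tat had 208 ± 127 and 743 ± 162 FPKM and the glycogen targeting gene Ppp1r3b 12.2 ± 1.31 and 34.0 ± 16.7, without passing. Igfbp1 had 10.5, 105 and 15.6 FPKM in diet replicates 0, 1 and 2 and 211 and 116 with dabigatran. The call was lost without any library other than diet replicate 1 (adjusted p = 0.0638, 0.0731, 0.0704 and 0.0540 without diet replicates 0 and 2 and dabigatran replicates 1 and 2, with medians of 0.40, 0.27, 0.44 and 0.20), and the median was 0.44 without diet replicate 1. It also ended with an FPKM of at least 5 (0.30), with the identical files counted as 2 libraries (0.31) and among genes with whole fragments only (0.27).

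The list of endoplasmic reticulum and amino acid stress had a median of 0.48 over 22 members, none of which passed by either adjustment (camera adjusted p = 0.0226, and adjusted p = 0.679 with an estimated correlation). Atf4 had 29.2 ± 5.86 FPKM in the diet group and 47.5 ± 3.28 with dabigatran, and Atf3 1.80 ± 0.713 and 0.535 ± 0.348. The groups overlapped for this list: diet replicates 1 and 2 lay at 0.30 and 0.14, and dabigatran replicates 1 and 2 at 0.22 and 0.62. The call was lost without diet replicate 0 (0.22, adjusted p = 0.161) or dabigatran replicate 2 (0.22, 0.216) and with a block on the replicate number (0.18), and diet replicate 0 stood lowest, at -0.39. Hepatocyte markers had a median of 0.16 over 24 members (camera adjusted p = 0.00586, and adjusted p = 0.679 with an estimated correlation), with none passing over all genes and 6 higher and 1 lower when adjusted over the list alone. The urea cycle genes Arg1 (439 ± 35.5 and 1256 ± 450 FPKM) and Cps1 (333 ± 119 and 1309 ± 683) and the tyrosine breakdown gene Hpd (1385 ± 243 and 3272 ± 1222) had higher values, and the urea cycle gene Otc lower ones (209 ± 19.1 and 125 ± 19.9). The hepatocyte call ended after quantile normalization (median 0.15) and among genes with whole fragments only (0.01), and the median was 0.36 without dabigatran replicate 1.

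Coagulation proteins made by the liver had a median of 0.16 over 25 members (camera adjusted p = 0.0425, and adjusted p = 0.679 with an estimated correlation), and none passed by either adjustment. F2, which encodes prothrombin, the precursor of the drug's target, had 458 ± 37.2 FPKM (SD, n = 3) in the diet group and 514 ± 66.3 (SD, n = 2) with dabigatran, with overlapping values and a log2 difference of 0.16 ± 0.18 (SE, adjusted p = 0.697). The fibrinogen chain genes had 1109 ± 127 and 1866 ± 301 FPKM (Fga, adjusted p = 0.145), 1744 ± 382 and 3159 ± 680 (Fgb, adjusted p = 0.163) and 1803 ± 415 and 2747 ± 451 (Fgg, adjusted p = 0.272). Plg, for plasminogen, had 449.8 ± 8.55 and 592 ± 4.53. The list's call was lost without diet replicate 0 (0.09, adjusted p = 0.198), diet replicate 2 (0.17, 0.111) or dabigatran replicate 1 (0.11, 0.218), with a block on the replicate number (0.09), without a variance trend (0.16) and among genes with whole fragments only (0.16). Of 17 genes for thrombin receptors and vascular regulators, 5 were measured, and their list was not called (median 0.22, camera adjusted p = 0.670). The thrombin receptor gene F2r had 12.1 ± 2.33 and 16.3 ± 0.760 FPKM (adjusted p = 0.375) and Thbd, for thrombomodulin, 0.840 ± 0.181, with 1.18 and 4.22 in the dabigatran libraries. The tissue factor gene F3, with 2.68 ± 0.440 and 1.03 ± 0.281, was the 1 member lower when adjusted over the list alone, and none passed over all genes.

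Fibrosis genes were not called as a list (13 measured, median -0.07, mean -0.01, camera adjusted p = 0.861 in the upward direction). Ctgf, a matricellular protein gene induced by TGF-beta, was the 1 member that rose, from 0.881 ± 0.260 FPKM (SD, n = 3) to 5.38 ± 0.696 (SD, n = 2; adjusted p = 0.0404). Adjusted over the list alone, Ctgf and Fn1 (89.2 ± 12.04 and 161 ± 17.9 FPKM) were higher and Col3a1 (5.35 ± 1.62 and 1.12 ± 0.237) lower. Col1a1, not tested, had 1.67, 0.461 and 2.54 FPKM in the diet libraries, 0.615 in dabigatran replicate 1 and was listed at 0 in replicate 2. Markers of stellate cells and fibroblasts (16 measured, median -0.17, camera adjusted p = 0.723), endothelial cells (20, 0.11, 0.481) and bile duct cells (5, 0.05, 0.598 in the downward direction, with a mean of -0.54) were not called as lists, and none passed over all genes. The stellate median was -0.26 without diet replicate 0, -0.09 without diet replicate 1 and -0.11 without dabigatran replicate 1, and the endothelial median was 0.07 without dabigatran replicate 2, with no call in any of them. Adjusted over each list alone, Lyve1 was higher (8.92 ± 1.53 and 20.9 ± 3.25 FPKM) and Krt23 lower (6.23, 3.51 and 6.75 FPKM in the diet libraries, listed at 0 and at 1.33 with dabigatran), and no stellate marker passed. Rgs5 and Col14a1 had the lowest p among stellate markers, with log2 differences of 0.65 and -0.60, and the endothelial marker Clec4g had -0.76.

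Cell cycle genes (9 measured, median -0.24, camera adjusted p = 0.176), oxidative phosphorylation genes (35, -0.06, 0.324) and circadian clock genes (17, -0.00, 0.861 in the downward direction, with a mean of 0.06) were not called as lists, and none passed over all genes. The clock median was -0.25 without dabigatran replicate 1, -0.16 without diet replicate 2, -0.07 without diet replicate 0 and -0.04 without dabigatran replicate 2, and the cell cycle median was -0.40 without diet replicate 1, with no call in any of them. The cell cycle list passed without a filter on low values (-0.43), and oxidative phosphorylation with the identical files counted as 2 libraries (-0.10). Ccnd1, for cyclin D1, was the 1 cell cycle gene lower when adjusted over the list alone (7.20 ± 2.33 and 1.65 ± 0.927 FPKM), and the inhibitor gene Cdkn1a had 7.21 ± 3.70 and 20.8 ± 15.6. No oxidative phosphorylation gene passed by either adjustment, with Ndufb8 at 107 ± 9.06 and 81.6 ± 6.81 and Ndufa2 at 136 ± 9.09 and 113 ± 9.43. Camera tests a shift in a common direction and cannot register opposite changes within a list. Fry's test of changes in either direction gave adjusted p of 0.00771 for clock, 0.0298 for cell cycle and 0.450 for oxidative phosphorylation genes. This test passed most lists, also that of stellate markers (adjusted p = 0.00771), none of which passed by either adjustment. It therefore shows nothing particular to clock or cell cycle genes. Clock genes differed in opposite directions when adjusted over the list alone: Dbp was lower (8.89 ± 3.87 FPKM, with 1.25 and 1.74 in the dabigatran libraries), and Per1 (1.18 ± 1.11 and 8.26 ± 2.31) and Arntl (4.70 ± 0.425 and 9.08 ± 0.0648) were higher. The clock repressor gene Nr1d1 had 23.4 ± 3.80 and 14.8 ± 2.08. Oxidative phosphorylation passed without dabigatran replicate 2 (median -0.21, adjusted p = 0.00497) and cholesterol synthesis likewise (0.23, adjusted p = 0.0153), while cytokines passed without dabigatran replicate 1 (-0.65, adjusted p = 0.0404).

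Genes with higher expression in male than in female liver had a median of 0.38 over 18 members (camera adjusted p = 0.0279, and adjusted p = 0.679 with an estimated correlation), with none passing over all genes and 5 higher and 2 lower when adjusted over the list alone. Serpina1e had 1209 ± 1350 FPKM in the diet group and 8240 ± 2498 with dabigatran, Selenbp2 75.6 ± 44.5 and 424 ± 166, and C6 64.7 ± 15.4 and 144 ± 14.9. Slc22a28 was lower, at 3.30, 2.60 and 2.73 FPKM in the diet libraries, 0.769 in dabigatran replicate 1 and listed at 0 in replicate 2. Of the windows of Serpina1e, Selenbp2 and Slc22a28, 34.6%, 43.9% and 53.9% are shared with related genes. Diet replicate 1 lay with the dabigatran libraries for this list, at 0.58 beside 0.21 and 0.54, and against -0.34 and -0.29 in diet replicates 0 and 2. The call was lost without diet replicate 2 (0.26, adjusted p = 0.0731), dabigatran replicate 1 (0.49, 0.1403) or dabigatran replicate 2 (0.19, 0.0918), and the median was 0.66 without diet replicate 1. It also ended with a block on the replicate number (0.32) and among genes with whole fragments only (0.33).

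**Figure D3:**
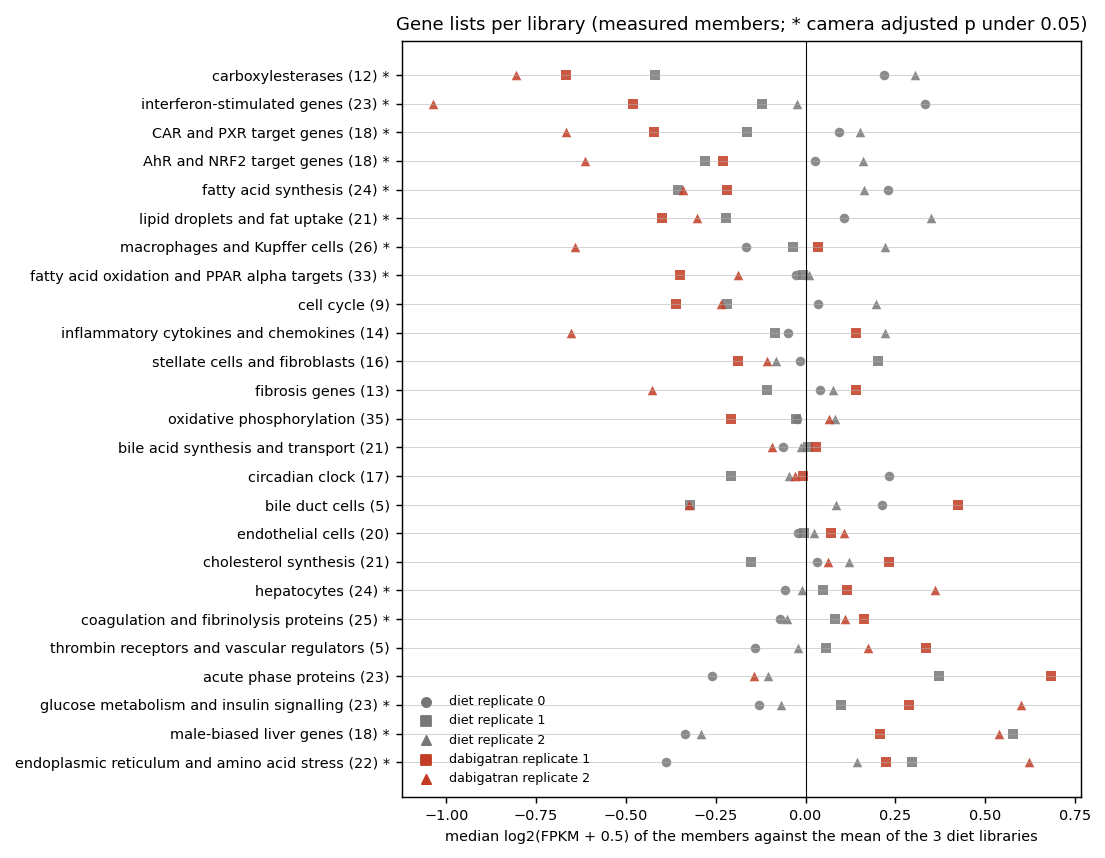
Median log2(FPKM + 0.5) of the measured members of each of 25 gene lists, against the mean of the 3 diet libraries, with 1 point per library (grey, diet; red, dabigatran), the number of measured members in parentheses and a star at lists with a camera adjusted p under 0.05. The interferon-stimulated genes lie at -0.48 and -1.04 in the dabigatran libraries, and the male-biased genes of diet replicate 1 lie at 0.58, beside the dabigatran libraries.

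The other 7 lists had fewer than 5 measured members and were not tested as lists. Of 4 adipocyte markers, Cfd and Car3 fell, while Adipoq had 0.320 FPKM in diet replicate 0 and was listed at 0 elsewhere. Of 4 female-biased genes, Cyp17a1 rose, and adjusted over the list alone 3 were higher and 1 lower. None of 3 neutrophil markers passed by either adjustment, and of 3 erythrocyte markers Alas2 was lower when adjusted over the list alone. The 1 lymphocyte marker measured, Coro1a, had a log2 difference of -0.29, and the 1 pancreatic acinar marker, Cela1, -0.55, which passed when adjusted over the list alone. No skeletal muscle marker was measured.

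With 3 and 2 libraries per group, simulated changes of 2-fold were recovered in 17.2% of genes and those of 4-fold in 82.6%, so that smaller differences were mostly not detectable. Of the 13 lists called with the preset correlation, 5 kept their call without each library in turn (fatty acid oxidation, interferon-stimulated genes, AhR and NRF2 targets, carboxylesterases and hepatocytes), and 0 of 25 passed with an estimated correlation. With fry's directional test, 1 of the 25 lists passed, fatty acid oxidation (adjusted p = 0.0170). The other lists called by camera had directional fry adjusted p from 0.247 to 0.579. Fry's test of changes in either direction passed bile acid and fibrosis genes too (adjusted p = 0.0147 each). By that test only the cytokine (0.205), acute phase (0.383), stress (0.376), male-biased (0.0564) and oxidative phosphorylation (0.450) lists did not pass.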

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

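Added after the data were seen were the filter with 2 libraries, the identical files counted as 2 libraries, the threshold of 0.10, the omission of genes listed at 0, voom, and the same fit on genes with whole fragments only. The planned count tests were not run, because the deposited unit is FPKM, and voom on recovered fragments stood in for them. None of the 103 genes named by the rule and tested changed direction under an alternative that measured it, and the genes named after their values were seen were not compared. Most of the 103 had groups whose libraries did not overlap. For these, leaving out a library, the block, or another pseudocount or filter could not reverse the direction, so this result says little about stability. Genes higher and lower, 13 and 31 as reported, numbered 5 and 8 with a block on the replicate number, 6 and 17 with a pseudocount of 0.1, 20 and 49 with a robust prior and 168 and 263 with the identical files counted as 2 libraries. They numbered 77 and 165 at a threshold of 0.10, 11 and 16 after quantile normalization, 8 and 27 with an FPKM of at least 5, and 10 and 10 with voom, which tested the 8295 genes with whole fragments. The limma fit on log2(FPKM + 0.5) of these same genes gave 14 and 30. Limma called 0 and 0 genes without a filter, with 816 and 1117 at an unadjusted p under 0.05, and 0 and 0 without a variance trend, with 692 and 870. Of the 44 called genes, 8 were shared with the block, 26 with quantile normalization, 41 with the robust prior and 20 with voom, where 39 of the 44 had whole fragments and could be shared. Across the libraries left out, genes higher ranged from 0 to 101, genes lower from 0 to 229 and lists called from 6 to 14, where a dabigatran library left alone is assumed to vary like the diet group. With an estimated correlation, camera called 0 lists. List medians with the opposite sign were 0.0046 (circadian clock) and -0.066 (bile duct) with the block, 0.0295 (bile acid), 0.0221 (circadian clock) and -0.0186 (bile duct) without a filter, 0.1298 (fibrosis) with an FPKM of at least 5, 0.0221 (circadian clock) with the filter of 2 libraries, and 0.012 (bile acid), 0.0622 (fibrosis) and 0.0836 (circadian clock) with the identical files as 2 libraries. Across the libraries left out, medians ranged from -0.0024 to 0.2327 for cholesterol synthesis, from -0.1236 to 0.028 for bile acid genes, from -0.6526 to 0.1408 for cytokines, from -0.1429 to 0.6821 for acute phase genes and from -0.4533 to 0.1327 for fibrosis genes. They ranged from -0.2085 to 0.0662 for oxidative phosphorylation, from -0.6405 to 0.0341 for macrophages and from -0.1762 to 0.4256 for bile duct markers. Across the other alternatives, medians ranged from 0.0682 to 0.1482 for cholesterol synthesis, from -0.1151 to 0.0295 for bile acid genes, from -0.3142 to -0.0161 for cytokines, from 0.0376 to 0.3965 for acute phase genes, from -0.2098 to 0.1298 for fibrosis genes, from -0.2345 to 0.0836 for clock genes, from -0.1048 to -0.029 for oxidative phosphorylation and from -0.066 to 0.1753 for bile duct markers. The cause was not tested. Libraries share only a number across the groups, and the deviations of same-numbered libraries from their group means had correlations across genes of -0.0448 and -0.0255.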

Other observations

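The gene lists of the first paragraphs, and the tests on macrophages, adipose tissue and a failed estimate of Cfd, were chosen after the values were seen. The lists were drawn up around genes already seen to differ, so their values are a description of these libraries and no test is given for them. Of 43 measured genes of the urea cycle and of amino acid breakdown, 33 had higher values with dabigatran and 10 lower, with a median log2 difference of 0.48. Sds and Sdsl rose over all tested genes, and the other members did not pass. The list lay at 0.34 and 0.58 in dabigatran replicates 1 and 2, and at -0.03, 0.04 and -0.04 in the diet libraries. The metallothionein gene Mt2 had 108, 225 and 133 FPKM in the diet libraries and 417 and 808 with dabigatran, beside the rise of Mt1.

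Of 7 measured MHC class II genes, 6 had lower values with dabigatran and 1 higher (median log2 difference -1.34), and of 18 MHC class I genes, 14 had lower values and 4 higher (median -0.16). No gene of these lists passed over all tested genes. The class II list lay at -1.06 and -1.30 in dabigatran replicates 1 and 2, and at 0.27, -0.45 and 0.20 in the diet libraries. The class I list overlapped, at -0.07 and -0.28 in dabigatran replicates 1 and 2 and at 0.06, -0.18 and 0.09 in the diet libraries. B2m, the light chain of MHC class I, had 1859, 1670 and 1870 FPKM in the diet libraries and 1260 and 998 with dabigatran. Of 9 clock genes of the Dbp arm, 6 had lower values and 3 higher (median -0.37). This list overlapped too, at -0.34 and -0.25 in dabigatran replicates 1 and 2 and at 0.26, -0.27 and -0.05 in the diet libraries.

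Diet replicate 1 lay between the other diet libraries and the dabigatran libraries on the first principal component. On the second, with 22.4% of the variance, it was the outermost library at -32.1. Diet replicates 0 and 2 lay there at 12.7 and 16.0, and dabigatran replicates 1 and 2 at -14.6 and 17.9. Lower depth of diet replicate 1 did not account for the intermediate place. Among 1072 genes with a mean FPKM of at least 50, its position was 0.694 on a scale with 0 at the other diet libraries. The 95% bootstrap interval, over genes and not mice, was 0.536 to 0.902. The scale was built from products of separate libraries, which leave out the spread between the dabigatran libraries. The mean of the dabigatran libraries therefore lies above 1 on it, and 0.694 overstates the plain share of the distance. On the same scale, each against its own other diet libraries, diet replicates 0 and 2 both lay at -1.14. As a plain share of the distance to the dabigatran mean, the median position of diet replicate 1 was 0.485 over the 266 genes called without it. Mice of both sexes were not seen, since the highest Xist value was 0.0430 FPKM and the sum of 4 Y-linked genes was 39.3 to 61.4 FPKM. A dabigatran mouse labelled as diet stays open: of 266 genes called without this library, 51.1% had it nearer the other diet libraries, while dabigatran replicate 1 was nearer its own group in 42.4% of the 330 genes called without it. No biological explanation was tested, since the design gives none within the group.

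Interferon-stimulated genes had lower values with dabigatran (median -0.88, bootstrap interval -1.01 to -0.73). None passed over all tested genes, and with an estimated correlation the list was not called (camera adjusted p = 0.679). The intervals here come from resampling list members, not mice. They do not cover the spread between the dabigatran libraries, where this list lay at -0.48 and -1.04. Fewer macrophages alone would lower their markers as much. The 22 markers without MHC class II genes had a median of -0.21 (interval -0.38 to 0.10), with -0.63 in dabigatran replicate 2 and 0.13 in replicate 1. In each of these libraries the markers lay above the interferon-stimulated list, but so few libraries cannot show whether further mice would differ likewise. With the MHC class II genes the marker median was -0.32. The omitted H2-Aa, H2-Eb1, H2-Ab1 and Cd74 had log2 differences of -1.59, -1.55, -1.34 and -0.98, so the comparison does not cover cells marked by these genes. Low FPKM did not account for the lower interferon-stimulated values in these libraries. The 7 members with a mean FPKM of at least 10 had a median of -0.92 (interval -0.96 to -0.80). The limit was set on FPKM and not on fragments. Of these members, Bst2 had 76 to 205 fragments per library, but Psmb8 only 4 to 45. Few fragments per gene therefore stay open for some members. Dabigatran itself stays open and untested, since only the same list in further mice of both groups would separate it from differences among these 5 libraries.

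The adipocyte markers Cfd and Car3 fell with dabigatran. Adipose tissue would bring other adipocyte transcripts. In diet replicate 0 the 7 other markers of the list, with the liver genes Pck1 and Thrsp left aside, summed to 0.948% of the Cfd value. Only 3 of them, Adipoq (0.213%), Retn and Nnat, were above 0 there. Lep, Plin1, Aqp7 and Slc36a2 were listed at 0, which can be failed estimates, so the sum can be too low. What speaks against adipose tissue in this library is therefore the low Adipoq, Retn and Nnat values alone. In diet replicates 1 and 2 adipose tissue stays open, since the sums of 4.36% and 1.31% rest on Adipoq and Retn listed at 0, and a 0 can be a failed estimate. The markers and the bound of 10% were changed more than once after the values were seen, and the sums depend on the set: with Fabp4, which is not on the list and had 29.3, 15.6 and 31.2 FPKM in the diet libraries and 16.0 and 34.3 with dabigatran, they were 20.4%, 59.5% and 67.1%. A failed estimate of Cfd itself stays open, since 1 other gene, Ndufs5, was listed at 0 in both dabigatran libraries and above 20 FPKM in a diet library, but it would not explain Car3, which was above 0 in all 5 libraries.

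The split by group called 44 genes, and the highest count of the other splits into 3 and 2 libraries was 20, with diet replicates 0 and 2 as the pair. With 10 splits in all, 1 of which called as many genes, the splits are too few for a share under 0.05.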
